A study of Mus musculus with 3 samples.

How the data were processed

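The data are single-cell RNA profiles of GFP-positive cells from 3 mouse brain tumours. Per the labels, the tumours arose after electroporation of mouse brains 1 or 2 days after birth with MADR constructs, which insert a transgene at a chosen locus, here a heterozygous reporter at Rosa26 that switches from tdTomato to GFP. The tumours were microdissected, dissociated mechanically and with enzymes, and sorted by flow cytometry. Libraries were made with the droplet-based 3′ kit of 10x Genomics (version 2 chemistry) and sequenced on a NextSeq500. STAR 2.5.1, Cell Ranger 1.3.0 and the mouse genome build mm10 are named in the submitters' processing notes. Which barcodes were kept as cells, and by what rule, is not given in the sources used here. A 3′ kit counts transcripts near their polyadenylation site, so a protein change far from it is not read.

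For each tumour the authors deposited whole-number UMI counts per gene and barcode (unit: counts), over 27999 entries, of which 1 is the transgene element WPRE. The labels do not say which construct carries it. The authors also deposited a normalised signal, which equals the count times the median total of that tumour divided by the cell's own total (largest difference 5e-12); the tool is not given in the sources used here. It was used only for that check, and every value below comes from the counts. Symbols shared by several identifiers (121 entries) were kept apart by identifier. Positions come from the GENCODE annotation of GRCm38, the same build as mm10, and were matched by gene identifier.

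The 3 tumours form 1 group. Nothing in the labels gives collection days or library batches, and tumour, animal, age and library cannot be told apart. Total counts were 47120617, 15231673 and 53551127 UMIs in tumours 1, 2 and 4, from 4958 to 79868, 2897 to 59955 and 4316 to 78955 UMIs per barcode. Median genes per barcode were 3348.5, 2289 and 2915.5, and median mitochondrial shares 4.74%, 6.24% and 5.58%. The libraries were distinct: Pearson's r of log2 CPM, across genes of summed counts, was 0.920 for tumours 1 and 2, 0.971 for 1 and 4, and 0.929 for 2 and 4. Intervals are exact 95% binomial for shares and exact Poisson for counts. They cover counting error only. A count of 0 is given with the limit of 3 counts.

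Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. The first filter removed 0, 3 and 0 barcodes and the second 25, 82 and 247. Scrublet in scanpy 1.11.5 called 0, 7 and 0 doublets, under 0.5% of cells in each tumour, against expected rates of 2.68%, 1.23% and 3.50%, so it was taken not to have worked and no cell was left out. Whether doublets were removed before deposit is not stated in the sources used here. An alternative left out the 90, 19 and 153 cells with the highest scores, the number that a rate of 0.8% per 1000 cells gives. Each tumour was clustered alone (10000 UMIs per cell, log scale, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1), with no integration.

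Clusters were named from 17 marker lists fixed before the data were examined. A list's score was the mean log2(CPM + 1) of its markers less the 10th percentile of that value over clusters. The percentile was taken over the clusters of all tumours for neural classes and of the same tumour for other classes. Neural names in a tumour thus depend on the other tumours as well, and the 2 kinds of score have different baselines. A cluster took the class with the highest score if that score was at least 2, at least 3 markers had 20 CPM or more, no class of another compartment scored 2 or more within 2 of it, and its 10 leading genes by fold (pseudocount 10 CPM) held no more markers of another class than of its own. In the last 2 conditions microglia, macrophages or monocytes and dendritic cells counted as 1 class. A microglia-like cluster could therefore be led by macrophage markers. These limits were set after marker levels had been seen and were revised 3 times before any differential test. They leave 29.0% of tumour 1 and 15.1% of tumour 4 unnamed for their leading genes alone; naming by marker level alone is an alternative. Neural cells are those of neural classes plus unnamed clusters whose only scores of at least 2 were neural, 3190, 1044 and 4300 cells.

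A correction was made after differential results had been seen. A single barcode of tumour 1 with 11365 UMIs, 80.1% of them haemoglobin (the next highest of that tumour had 0.154%), had kept a cluster of 548 cells from being named. Barcodes over 10% haemoglobin were therefore left out of the profile used for naming. The former way is kept as an alternative; it gave 75 calls rather than 84 for oligodendrocyte-like cells and 0, as after the correction, for astrocyte-like cells. A haemoglobin signal had also been weighed with 2 tests, which were dropped once it proved to come from this barcode.

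Cells were thinned at random to 2000 UMIs to call cycling: at least 5 UMIs of 53 measured cycling genes, with non-cycling cells at most 1. No neural cell was too shallow. Gene levels are CPM of UMIs summed over the neural cells of a tumour.

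Differential tests used edgeR 4.0.16 in R 4.3.3: the quasi-likelihood test on UMI sums per tumour and class of at least 20 cells, with TMM scaling, filterByExpr, tumour as a block and Benjamini-Hochberg adjustment at 0.05. Sums from the same animal are paired by the animal itself. The cycling test had 6 sums and the class tests 9 sums in 1 fit, each with 2 residual degrees of freedom. Genes that define the cells compared were left out of counts and names: the cycling list in the cycling test and all cell type markers in the class tests. SE is the absolute log2 fold change divided by the square root of the F statistic. DESeq2 1.42.0 was an alternative. Of 23 gene lists fixed before the data were examined, 21 had at least 3 testable members in each test; Hox genes did not, nor the cycling list where it defines the cells, nor the engineered genes where Pdgfra is a marker. Lists were tested with camera (correlation 0.01, and again with an estimated one) and fry in limma 3.58.1.

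Simulated counts had 200 changed genes, drawn once from those with a mean of at least 20 CPM, so recovery is known for such genes only. The cycling test recovered 73% of genes changed 2-fold and 100% of those changed 4-fold, with 14354 genes tested, and 10.8% of its 194 calls were false. The astrocyte-like test recovered 5% and 71% over 11127 genes with 11.6% of 86 calls false, and the oligodendrocyte-like test 8% and 86% over 11156 genes with 11.3% of 106 calls false. The tests thus exceed their nominal 5% of false calls.

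Named genes followed a rule fixed before the data were examined: for each test the 10 called genes with the largest change each way, of the same direction in every tumour compared and a mean of at least 20 CPM, plus up to 4 members of each list described with the smallest p. Between tumours these were the 8 genes with the largest ratio among those with at least 100 CPM in a tumour, plus a fixed set of markers. Gene models without a name were passed over, and a few genes that the rule gives are left out of the text and figures for reasons unrelated to their values. WPRE and the Y-linked genes were added after their values were seen, as were the ratios of 8 for genes and 2 for lists. A test of depth for WPRE was dropped because it restated its levels. Alternatives changed 1 choice at a time, with limits that belong together, such as genes and mitochondrial share or the cycling and non-cycling limits, moved together. Among them were cell filters, resolution, joint clustering, clusters made from UMIs drawn at random with a chance of 0.5 and tests on the rest, thinning, scaling, filters on low counts, the block, and each tumour left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 did the rest.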

Results

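Single-cell RNA sequencing was performed on GFP-positive cells sorted from 3 mouse brain tumours that share 1 genotype, here called tumours 1, 2 and 4 after the numbers in the labels. The tumours grew after electroporation of the newborn brain with constructs for 3 altered proteins: histone H3.3 (H3f3a) K27M, the receptor tyrosine kinase Pdgfra D842V and the tumour suppressor Trp53 R270H. The labels call the tissue a paediatric brain glioma. Tumour 1 was collected at postnatal day 150, tumour 2 at day 106 and tumour 4 at day 149. The tables held 3386, 1632 and 4624 cell barcodes, with 47120617, 15231673 and 53551127 unique molecular identifiers (UMIs). The median barcode had 11908.5 UMIs in tumour 1, 7570.5 in tumour 2 and 9102.5 in tumour 4. After filtering, 3361, 1548 and 4377 cells remained. With 1 genotype and 1 library per tumour, the design gives no comparison of genotypes and no test between tumours, so differences between tumours are given as values whose intervals cover counting error only, and tests were made between cell states within tumours.

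The first question was which cell types each tumour held. Cells resembling oligodendrocyte progenitor cells (OPCs) were the largest named class in tumours 1 and 4, at 64.8% (exact binomial 95% interval 63.2 to 66.4) of cells in tumour 1 and 73.4% (72.1 to 74.7) in tumour 4. Only 9.04% (7.66 to 10.6) of tumour 2 was OPC-like, which gave 49.1% ± 35.0 (SD, n = 3). Oligodendrocyte-like cells, carrying myelin genes such as Mbp, Mag and Mog, made up 39.0% (36.6 to 41.5) of tumour 2 and 9.76% (8.89 to 10.7) of tumour 4. None of the 3361 cells of tumour 1 was in this class (limit of 3 counts, 0.0893%). Astrocyte-like cells made up 10.3% (8.80 to 11.9) of tumour 2 and 1.07% (0.751 to 1.48) of tumour 1, and 0 of 4377 cells in tumour 4 (limit of 3 counts, 0.0685%). Classes were given to whole clusters, the smallest of tumour 1 with 10 cells. These limits are therefore no bound on single cells of a class.

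Immune cells had passed the sort for GFP in all 3 tumours. Microglia-like cells made up 25.5% (23.4 to 27.8) of tumour 2, 4.79% (4.09 to 5.57) of tumour 1 and 1.76% (1.39 to 2.19) of tumour 4. The share of tumour 2 was 13.6% with halved UMIs and 17.7% without the cells of highest Scrublet score (chosen after seeing the data), and that of tumour 1 was 2.92% with a stricter filter on cells. In tumour 2 the leading genes of these clusters held C1qa and C1qc. The microglia-like cluster of tumour 1 was led by Cxcl2, Il1b and the macrophage markers Lyz2 and Cd74, and by no microglia marker. It scored 5.63 for microglia, 2.74 for macrophages or monocytes and 2.57 for OPCs, so its name does not part microglia from macrophages. In tumour 2 alone, classes were named for 100 committed OPC-like cells (6.46%), 41 neuroblast-like cells (2.65%), 25 endothelial-like cells (1.61%) and 19 T or NK cell-like cells (1.23%). The remaining 29.3% of tumour 1, 4.20% of tumour 2 and 15.1% of tumour 4 stayed unnamed. In tumour 1, 975 of those cells lay in 3 clusters with OPC markers whose leading genes held neuronal markers such as Nefl and Nefm, and in tumour 4, 659 cells lay in 2 clusters with OPC markers whose leading genes held Nefl or Igf2. A further 10 unnamed cells of tumour 1 formed a cluster of mixed markers, led by genes such as Nkg7, Cd3g and Rgs5. It scored 5.98 for T or NK cells, 5.64 for mural and 4.09 for endothelial cells. T or NK and vascular markers were thus not confined to tumour 2. The intervals of the tumours did not overlap for OPC-like, oligodendrocyte-like, astrocyte-like or microglia-like cells.

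**Figure D1:**
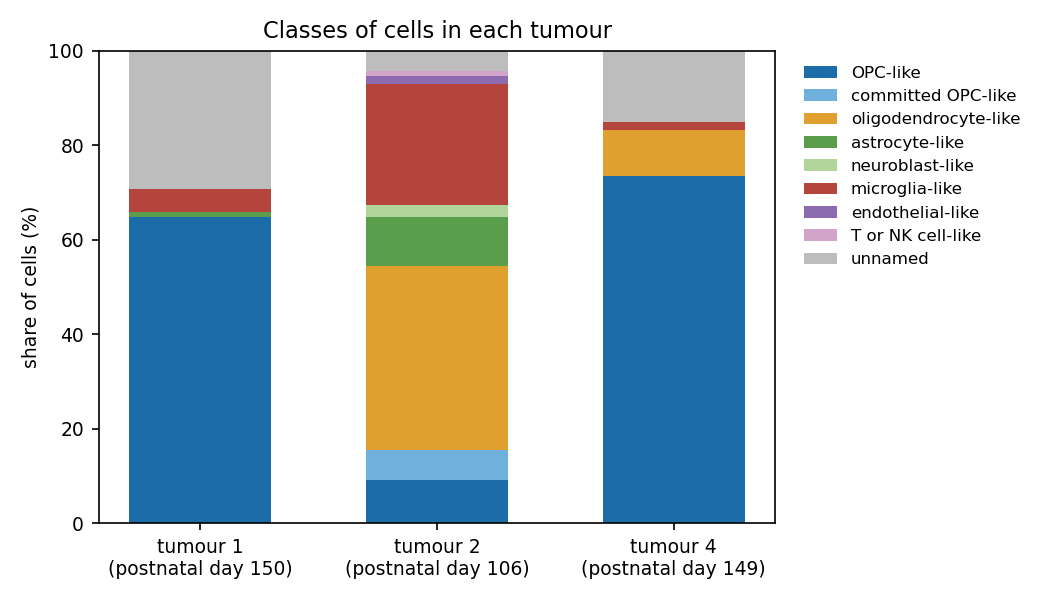
Share of cells (percent, vertical axis from 0) in each class for tumours 1, 2 and 4 (stacked bars, intervals in the text, unnamed cells in grey). OPC-like cells were 64.8% of tumour 1 and 73.4% of tumour 4 but 9.04% of tumour 2, where oligodendrocyte-like cells were 39.0% and microglia-like cells 25.5%.

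The oligodendrocyte-like class was not alike in the tumours. In tumour 4, 394 of its 427 cells lay in a cluster led by Ptgds, Gjb1 and Cldn11 that also carried OPC markers, and 33 lay in a cluster led by Ppp1r14a, Mog and Mobp. In tumour 2 it comprised 6 clusters, of which 1, with 22 cells, was led by the stress genes Mdm2, Gdf15, Ddit4 and Txnip. The 159 astrocyte-like cells of tumour 2 were led by Egr4, Cxcl10 and Ccl2 besides Mlc1 and Mt3, at a median of 11.4% mitochondrial UMIs. Their name rests on a close marker score, 3.69 for astrocytes against 3.42 for oligodendrocytes and 2.95 for OPCs. In tumour 1 the astrocyte-like cells scored 4.53 against 2.19 for OPCs. The committed OPC-like cells of tumour 2 scored 4.28 for their class against 4.26 for OPCs. Interferon-responsive Gbp2 and Bst2 led 3 OPC-like clusters of tumour 4. Naming depended on how clusters were made. With the tumours clustered together, the mean OPC-like share was 0% and the oligodendrocyte-like share 36.9%. The mean unnamed share was then 50.6%, against 16.2% in the main naming. The OPC-like share of tumour 1 was 93.8% with clusters named by marker level alone (chosen after seeing the data), 45.5% with a stricter filter on cells and 38.3% with halved UMIs. That of tumour 2 was 0% at resolution 0.5 and 22.2% without the cells of highest Scrublet score (chosen after seeing the data). The oligodendrocyte-like share of tumour 2 was 16.2% at resolution 0.5. In tumour 4 it was 82.4% with the tumours clustered together, and fell to 0.754% at resolution 0.5, to 2.51% with no filter on cells and, in alternatives chosen after seeing the data, to 0.754% without haemoglobin genes in clustering and 1.73% without the highest Scrublet scores. The committed OPC-like class of tumour 2 was not found with no filter on cells, at resolution 0.5, with joint clustering, or in the alternatives on Scrublet scores and haemoglobin genes, and was 11.3% at resolution 2; joint clustering gave it 53 cells in tumour 1. The endothelial-like class was 3.23% with halved UMIs and was not found at resolution 0.5 or with joint clustering, which named no neuroblast-like, T or NK cell-like or astrocyte-like cells either. The astrocyte-like share of tumour 1 was 2.32% at resolution 0.5 and 2.47% with halved UMIs. An ependymal-like class, absent from the main naming, was named with a stricter filter on cells (mean share 0.983%) and with halved UMIs (0.609%). The astrocyte-like class of tumour 2 was not found with no filter on cells, with a stricter one, at resolution 0.5, with joint clustering, or in the alternatives on Scrublet scores and haemoglobin genes, and was 2.91% at resolution 2.

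A share of the neural cells carried the transcripts of dividing cells in each tumour. At an equal depth of 2000 UMIs per cell, 30.5% (exact 95% interval 28.9 to 32.1) of 3190 neural cells in tumour 1 had at least 5 UMIs of the cycling genes, a list with Mki67, Top2a and Cdk1. The share was 10.4% (8.65 to 12.5) of 1044 cells in tumour 2 and 22.5% (21.2 to 23.8) of 4300 cells in tumour 4, a mean of 21.1% ± 10.1 (SD, n = 3). OPC-like cells gave 949 of the 972 cycling cells of tumour 1 and 906 of 967 in tumour 4, but 40 of 109 in tumour 2. Within the OPC-like class 43.6% of cells cycled in tumour 1, 28.6% in tumour 2 and 28.2% in tumour 4. The first of these rests on the naming rule, since unnamed cells, nearly all with OPC markers, reached 2.34% in tumour 1 and 6.22% in tumour 4. Oligodendrocyte-like cells reached 4.64% in tumour 2 and 4.68% in tumour 4, committed OPC-like cells 1.00%, and astrocyte-like cells 19.5% in tumour 2 and 2.78% in tumour 1. Neuroblast-like cells of tumour 2 reached 22.0%, on 41 cells. Microglia-like cells, not counted among the neural cells, gave 16.1% in tumour 1, 0.759% in tumour 2 and 9.09% in tumour 4, at median depths of 13611, 7219 and 8812 UMIs before thinning. The shares of astrocyte-like cells in tumour 1, of oligodendrocyte-like cells in tumour 4 and of unnamed cells in both lay below those of microglia-like cells of the same tumour, and the interval of committed OPC-like cells in tumour 2 (0.0253 to 5.45) held the share of its microglia-like cells, so background is not excluded for any of them.

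Shares by class are partly circular, since the clusters were made with cycling genes among the variable genes. Free RNA was not removed, and microglia can divide themselves, so they are not a clean measure of it. Cells with 2 to 4 UMIs of the list, 23.9% of tumour 1, 8.72% of tumour 2 and 16.0% of tumour 4, lay between the cycling and non-cycling classes. The mean share was 49.4% without thinning, 14.0% when 10 UMIs were required and 33.4% in OPC-like cells alone, the last chosen after seeing the data.

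The 3 engineered genes were transcribed in every tumour. H3f3a (ENSMUSG00000060743, chromosome 1, 180800832 to 180813943, minus strand, mm10) had 1482 CPM (counts scaled to a common total) in the neural cells of tumour 1, 888.1 in tumour 2 and 1314 in tumour 4, a mean of 1228 ± 306.2 (SD, n = 3). Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215, plus strand) had 122.5, 28.7 and 76.9 CPM, a mean of 76.1 ± 46.9 (SD, n = 3). Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand) had 125.7, 72.0 and 93.0 CPM, a mean of 96.9 ± 27.1 (SD, n = 3). The sums of Pdgfra and H3f3a depended on the mix of classes. In OPC-like cells alone Pdgfra had 137.8, 155.3 and 79.4 CPM in tumours 1, 2 and 4, and H3f3a had 1484, 1447 and 1322. Tumour 2 was thus no longer the lowest for either gene. Its Pdgfra interval (132.0 to 181.5, from 158 UMIs) overlapped that of tumour 1 (133.7 to 142.0), and Pdgfra is itself a marker of the class. Trp53 changed little, at 126.2, 69.8 and 97.3 CPM, with tumour 2 still lowest. The 3′ tags may not tell the transgenes from the native genes, and H3f3a has near-identical copies, so these levels do not check the constructs. The locus of the cell cycle inhibitors p16 and p19, Cdkn2a, was transcribed at 159.1, 67.5 and 206.7 CPM in tumours 1, 2 and 4, and at 145.7, 32.4 and 199.9 CPM in OPC-like cells alone.

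Markers of glial cells differed between the tumours as well. The proteoglycan Cspg4 of OPCs had 33.6 CPM in tumour 1, 8.92 in tumour 2 and 43.8 in tumour 4, while myelin Mbp had 200.5, 9336 and 1422. Olig2, a transcription factor of the oligodendrocyte lineage, differed little, at 209.0, 200.2 and 324.3 CPM. The astrocyte filament Gfap stood at 112.8, 213.9 and 194.1 CPM, and the water channel Aqp4 at 9.54, 26.0 and 1.87 CPM. Mki67 and Top2a, both of dividing cells, had 65.2 and 196.4 CPM in tumour 1, 29.9 and 51.6 in tumour 2, and 30.8 and 113.6 in tumour 4. In OPC-like cells alone tumour 2 was not the lowest for these genes, with Mki67 at 86.3, 109.1 and 38.3 CPM and Top2a at 263.7, 227.0 and 141.3 in tumours 1, 2 and 4. Cspg4 stood at 37.2, 28.5 and 44.4 CPM in those cells. The interval of tumour 2 (19.1 to 40.9, from 29 UMIs) overlapped that of tumour 1 (35.1 to 39.4).

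Of 23 gene lists, 7 differed by at least 2-fold between the highest and the lowest tumour, over all neural cells. Summed over their members, cycling genes had 2958 CPM in tumour 1, 990.3 in tumour 2 and 2081 in tumour 4, and ribosomal protein genes 82532, 31325 and 66025. Mesenchymal and matrix genes, among them Vim, Lgals1 and S100a6, had 4991 CPM in tumour 1, 2464 in tumour 2 and 9117 in tumour 4. Tumour 2 stood highest for cholesterol synthesis genes at 1653 CPM, against 424.0 in tumour 1 and 635.6 in tumour 4, for immediate early and dissociation genes at 10244 against 3796 and 6269, and for Wnt pathway genes at 88.0 against 37.7 and 50.6. Hox genes were near the detection limit: none of the 29 reached 1 CPM in any tumour, and their sum was 2.32 CPM in tumour 2. Without tumour 2 only 1 list differed by 2-fold, the Hox genes, at 0.0453 CPM in tumour 1 and 0.137 in tumour 4 with overlapping intervals, so no list above the detection limit did, and without tumour 1 the number was 5.

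Within OPC-like cells alone (chosen after seeing the data) 11 lists differed by 2-fold. Cycling genes (ratio 1.53) and ribosomal protein genes (1.56) were no longer among them, while interferon response (2.72), stem and progenitor (2.97), Notch (2.48), Polycomb-silenced (2.78), synaptic (2.23) and glycolysis genes (2.07) were. Over all neural cells other lists lay closer together. Interferon response genes had 3342 CPM in tumour 1, 4348 in tumour 2 and 6359 in tumour 4, and MHC class I genes 7151, 9016 and 10808. Targets of p53 had 1164, 2136 and 1808 CPM, and subunits of Polycomb repressive complex 2 (PRC2, which methylates K27 of histone H3) with the K27 demethylases 496.9, 648.0 and 548.4 CPM. All of these values hold different mixtures of the classes.

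Single genes reached larger ratios between the tumours than the lists did. The largest ratio was that of Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), the RNA that silences an X chromosome in females, with 2247 CPM in tumour 1, 0.837 in tumour 2 and 0.293 in tumour 4. Next stood the casein gene Csn2, with 114.9 CPM in tumour 2, 0.332 in tumour 4 and 0.0453 in tumour 1, where it rested on 2 UMIs, and the imprinted RNA Meg3, with 842.2 CPM in tumour 4, 86.0 in tumour 2 and 0.680 in tumour 1. The myelin genes Mag and Mog, the lipid carrier Apod and the matrix gene Mgp, also among the largest ratios, were highest in tumour 2. Mag had 1214 CPM there against 1.93 in tumour 1 and 71.0 in tumour 4, Mog 966.4 against 2.06 and 19.7, Apod 3885 against 4.96 and 93.0, and Mgp 352.9 against 1.63 and 0.684. Among 2004 genes with at least 100 CPM in a tumour, 170 differed by at least 8-fold; in OPC-like cells alone it was 76 of 1828.

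Y-linked genes mirrored Xist over all cells. Ddx3y had 0 UMIs in tumour 1, 1257 in tumour 2 and 2440 in tumour 4, and Eif2s3y 0, 1164 and 3843. Xist itself had 105873, 11 and 15 UMIs. The labels used here give no sex for the mice. Tumour 1 thus differed from tumours 2 and 4 in its sex-linked transcripts.

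Cycling neural cells differed from non-cycling ones in 564 of 14586 tested genes outside the defining list, 501 of them higher and 63 lower in cycling cells (edgeR's quasi-likelihood test on sums per tumour, tumour as a block, Benjamini-Hochberg adjusted p under 0.05, n = 3 pairs). The kinetochore scaffold Casc5 (ENSMUSG00000027326) was higher by a log2 fold change of 5.22 ± 0.33 (SE, adjusted p = 0.00178), and the cohesin protector Sgol2a by 5.18 ± 0.29 (adjusted p = 0.00178). Sgol1, Neil3, Fam64a, Aspm, Ska1, Cdca2, Ect2 and Cdc25c followed, at log2 fold changes from 4.61 (Cdc25c) to 5.05 (Sgol1). All 10 were higher in each of the 3 tumours, as the rule for naming required.

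Genes lower in cycling cells changed less. The small heat shock genes Hspb1 and Cryab had log2 fold changes of -1.56 ± 0.22 (SE, adjusted p = 0.0151) and -1.18 ± 0.23 (adjusted p = 0.0476). The surface proteins Ly6a and Ly6c1 stood at -1.47 ± 0.18 and -1.45 ± 0.17, the receptor Ephb1 at -1.48 ± 0.25, and Vamp5, Tmem88b, Tmem150a and Slc24a2 between -1.31 (Slc24a2) and -1.45 (Vamp5). Each was lower in all 3 tumours, again by the rule for naming. Among OPC-like cells alone, where the mix of classes does not enter, Ephb1, Ly6a, Ly6c1 and Slc24a2 were not called (adjusted p between 0.0953 for Ly6a and 0.701 for Ephb1). Their direction held, and a lost call alone does not show that the mix of classes made the change. That test called 855 genes lower, against 63 over all neural cells. Ephb1 and Slc24a2 were also among the genes named as higher in oligodendrocyte-like than in OPC-like cells. Of oligodendrocyte-like cells 4.64% cycled in tumour 2 and 4.68% in tumour 4, against 28.6% and 28.2% of OPC-like cells. The mix of classes thus stays a candidate for both genes.

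**Figure D2:**
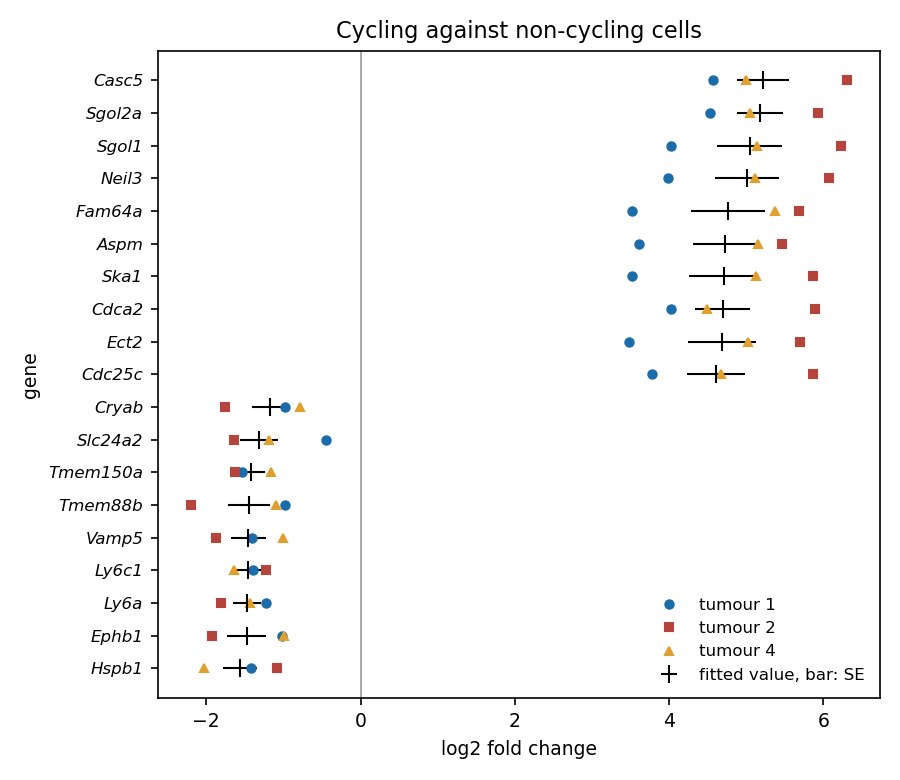
Log2 fold change of each named gene, cycling over non-cycling neural cells, per tumour (points, scaled log2 CPM differences) and fitted over the 3 tumours (bar, ± 1 SE). Genes such as Casc5 (5.22) stand to the right, and Hspb1 (-1.56) and Cryab (-1.18) to the left.

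The engineered genes themselves did not pass the test. Trp53 had a log2 fold change of 0.61 ± 0.21 (adjusted p = 0.191), Pdgfra of 0.31 ± 0.23 (adjusted p = 0.494) and H3f3a of 0.07 ± 0.14 (adjusted p = 0.817). The signs of Pdgfra and H3f3a turned with the sums of thinned UMIs and in OPC-like cells alone, where Pdgfra stood at -0.29 and H3f3a at -0.05.

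Among the gene lists, PRC2 subunits with the K27 demethylases were higher in cycling cells. Of the 13 tested members 3 rose, and 5 when adjusted over the list alone: the methyltransferase Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341, minus strand) by 1.85 ± 0.17 (SE, adjusted p = 0.00263), its partner Suz12 by 1.20 ± 0.15 (adjusted p = 0.00956) and the accessory subunit Phf19 by 3.09 ± 0.36 (adjusted p = 0.00629). The list passed camera (adjusted p = 0.0247) and fry (adjusted p = 0.0256), with an adjusted p = 0.855 with an estimated correlation. The p53 target list was also called by camera (adjusted p = 0.00440), with adjusted p = 0.855 with an estimated correlation. None of its 22 members passed the test over all genes and 1 did when adjusted over the list alone; the closest were Pidd1, at 1.86 (adjusted p = 0.0510), and Gdf15, at 2.54 (adjusted p = 0.128). Tumour 2 stood apart in both, with Pidd1 at 3.12 against 1.60 in tumour 1 and 1.22 in tumour 4, and Gdf15 at 4.75 against 1.64 and 1.25.

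Interferon response genes were lower in cycling cells by camera (adjusted p = 0.00440; adjusted p = 0.855 with an estimated correlation). Of 20 members 0 passed over all genes and 7, all lower, when adjusted over the list alone, with Gbp2 at -0.79, Ifit3 at -0.87, Irf7 at -0.68 and Oas1a at -0.67. Stem and progenitor genes were higher by camera (adjusted p = 0.0247; adjusted p = 0.855 with an estimated correlation), with 0 of 14 members called over all genes and 4 when adjusted over the list alone. Hes1 stood at 1.07, Pax6 at 1.79 and Nfib at 0.74. Single members of other lists passed the test: Nrarp of the Notch pathway rose by 1.51 (adjusted p = 0.0238), while Bnip3 of the hypoxia list stood at -0.94 (adjusted p = 0.0394) and Lgals3 of the mesenchymal list at -0.87 (adjusted p = 0.0447). The other 17 lists were not called, with camera adjusted p between 0.109 and 0.806.

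The number of calls moved with the tumours and settings. Without tumour 1 it was 343, and Hspb1, Cryab, Ephb1, Ly6a, Ly6c1, Vamp5, Tmem88b, Tmem150a, Slc24a2, Suz12, Bnip3 and Lgals3 lost their calls (adjusted p from 0.0512 for Ly6a to 0.449 for Lgals3). Without tumour 4 Slc24a2, Bnip3 and Lgals3 did (0.111, 0.136 and 0.199). Without tumour 2 there were 4338 calls (2288 higher and 2050 lower), in OPC-like cells alone 2085 (1230 higher and 855 lower), with DESeq2 859 (634 higher and 225 lower), and without the block 132, all higher.

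Oligodendrocyte-like cells were compared with OPC-like cells in tumours 2 and 4, the tumours that held both, leaving the marker genes of the classes out of the counts. They differed in 84 of 11822 genes, 52 higher and 32 lower in oligodendrocyte-like cells (edgeR's quasi-likelihood test, n = 2 tumours). Tmem125 (ENSMUSG00000050854, chromosome 4, 118540941 to 118544044, minus strand), which encodes a transmembrane protein, was higher by a log2 fold change of 4.01 ± 0.36 (SE, adjusted p = 0.0101). The tight junction gene Cldn14 at 4.01 ± 0.45 (adjusted p = 0.0240), the receptor Gpr62, Mgp, the exchanger Slc24a2, Cdc42ep2, the protease Klk6, Ephb1 and the septin Sept4 were higher too, down to 3.40 for Sept4.

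Mitotic genes were lower in the oligodendrocyte-like cells. Fam64a stood at -3.64 ± 0.50 (SE, adjusted p = 0.0281), the centromere histone Cenpa at -3.56 ± 0.46 and the spindle gene Aspm at -3.38 ± 0.40. Nusap1, Cdca3, Cdca8, Cdc20, Ube2c, Birc5 and Prc1 lay between -3.63 (Nusap1) and -3.12 (Prc1). The cycling list had 17 of its 52 tested members lower, and 47 when adjusted over the list alone, with Ccnb2 at -3.05 and Cenpe at -2.82 (camera adjusted p = 1.32e-27; adjusted p = 0.541 with an estimated correlation). All named genes had the same direction in both tumours, which the rule required of those named for the largest changes. With finer clusters (resolution 2) the signs of Nusap1, Aspm, Cdca8, Birc5, Prc1 and Cenpe turned, to log2 fold changes between 0.11 (Birc5) and 0.36 (Cenpe). The fall of mitotic genes is partly circular, since cycling genes were among the variable genes that made the clusters. An OPC-like cluster of 555 cells in tumour 4 was led by Cenpa, Ube2c, Birc5, Cdca3 and Fam64a, among others. In tumour 2 the leading genes of the OPC-like cluster held Cdca3 and Cenpa. The p-values of these genes and of the cycling list are therefore too small.

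**Figure D3:**
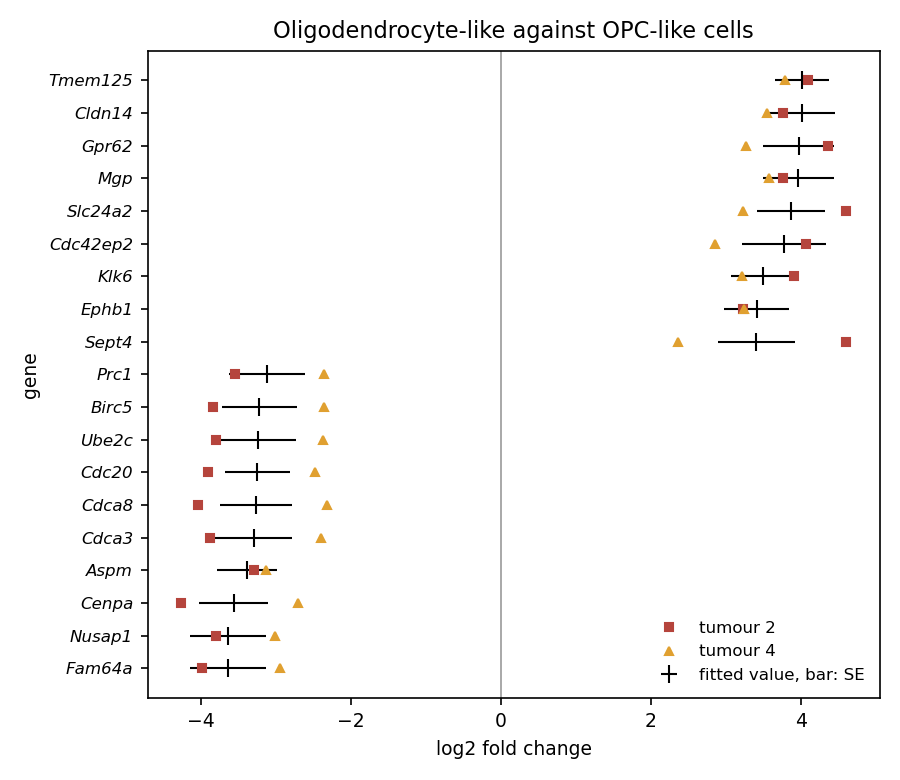
Log2 fold change of each named gene, oligodendrocyte-like over OPC-like cells, in tumours 2 and 4 (points, scaled log2 CPM differences) and fitted (bar, ± 1 SE). Tmem125 (4.01) and Cldn14 (4.01) stand to the right, and the mitotic genes, from Fam64a (-3.64) to Prc1 (-3.12), to the left.

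Camera called 12 of 21 lists in this comparison, 0 of them with an estimated correlation, where the lowest adjusted p was 0.541 with an estimated correlation. Apart from the cycling genes, no list had a member called over all genes, so members are given as values. Lower lists were stem and progenitor genes (camera adjusted p = 9.78e-05, 10 of 14 members lower when adjusted over the list alone), with Pax6 at -3.19, Egfr at -2.88, Nfib at -1.54 and Hes5 at -1.56, and the Notch pathway (0.00354), with Notch1 at -1.36 and Nrarp at -2.23; adjusted p = 0.541 for both with an estimated correlation. Receptor tyrosine kinase and MAPK output genes were lower as well (0.00111), with Dusp5 at -1.36 and Spry2 at -1.38, as were BMP and Id genes (0.0186), with Bmp2 at -1.94, again with adjusted p = 0.541 with an estimated correlation. Ribosomal protein genes (0.000411), immediate early genes (0.00244) with Egr1 at -2.00 and Fosb at -1.65, synaptic genes (0.0384) with Grm5 at -2.22, and PRC2 subunits with K27 demethylases (0.0439) with Phf19 at -3.39 and Ezh2 at -0.92 were lower, and had adjusted p = 0.689 with an estimated correlation.

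Cholesterol synthesis genes were higher in oligodendrocyte-like cells (camera adjusted p = 0.00493; adjusted p = 0.541 with an estimated correlation), with Mvk at 1.20. Hypoxia genes (0.0496) with Ndrg1 at 2.59 and Bnip3 at 1.28, and glycolysis genes (0.0439) with Aldoa at 1.01, were higher by camera too, with adjusted p = 0.541 with an estimated correlation. In the list of Polycomb-silenced growth genes, which camera did not call (adjusted p = 0.834), 2 of 6 members were higher and 2 lower when adjusted over the list alone, among them Cdkn1c at 1.70 and Hmga2 at -1.18; the median of the list was 0.11, while camera's direction was down. The other lists not called had camera adjusted p of at least 0.128.

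These calls rest on few sums, since the fit of 9 sums left 2 residual degrees of freedom, and on classes made from the same cells. With clusters made from some of the UMIs and tests on the rest, 628 genes were called, 83 of the 84 among them. The classes changed in that setting too, with a mean unnamed share of 30.1% against 16.2%. Its calls therefore do not show how much the double use of the cells mattered. The lower genes depended on the settings: at resolution 2 there were 78 calls, 38 of them shared, and with a stricter filter on cells 15, and in both settings 0 of the calls were lower. Without tumour 1, which held no oligodendrocyte-like cells but adds to the estimate of the spread, edgeR called 0 genes (1350 at an unadjusted p under 0.05) and each named gene lost its call (adjusted p from 0.114 for Tmem125 to 0.160 for Sept4); without tumour 4, where tumour 2 alone held both classes and the other sums gave the spread, it called 1723, and without the block 0 (1222 unadjusted). WPRE, a viral element used in transgenes that has its own entry in the tables, had 266.1 CPM in oligodendrocyte-like and 687.0 in OPC-like cells of tumour 2, and 595.7 against 847.1 in tumour 4.

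Astrocyte-like cells were compared with OPC-like cells in tumours 1 and 2. No gene passed the adjusted threshold: edgeR's quasi-likelihood test called 0 of 11822 genes, with 933 at an unadjusted p under 0.05, and DESeq2 called 78. The list members with the smallest p-values outside the cycling genes were Lfng, which modifies Notch receptors, at a log2 fold change of 3.36 ± 0.49 (SE, adjusted p = 0.167), the repressor Hes5 at 2.91 ± 0.42 (adjusted p = 0.167), the glutamate receptor Gria1 at 2.54 ± 0.39 (adjusted p = 0.167) and the BMP target Id1 at 2.55 ± 0.46 (adjusted p = 0.293). Each was higher in both tumours.

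Camera called 10 of 21 lists, 0 of them with an estimated correlation. Higher in astrocyte-like cells were stem and progenitor genes (adjusted p = 0.00311) with Sox9 at 2.27 ± 0.56 (SE, 3.40 in tumour 1 and 0.98 in tumour 2), Hes1 at 1.64 ± 0.43 (0.78 and 2.26) and Fabp7 at 3.21 ± 1.37 (5.57 and 0.42), the Notch pathway (0.0194) with Nrarp at 2.59, and BMP and Id genes (0.0143) with Id2 at 1.28, each with adjusted p = 0.585 with an estimated correlation. When adjusted over the list alone, 3 of 14, 2 of 12 and 3 of 10 members of these lists were higher. Interferon response genes (0.000215) with Ifitm3 at 1.54, MHC class I genes (0.00321) with Tap2 at 1.28 and H2-Q4 at 0.80, and mesenchymal and matrix genes (0.00126) with Sparc at 2.49 and S100a11 at 1.83 were higher by camera, again with adjusted p = 0.585 with an estimated correlation. Cytokine genes led the astrocyte-like cluster of tumour 2, at a median of 11.4% mitochondrial UMIs.

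Hypoxia genes (0.0194) with Egln3 at 2.07 and Pfkfb3 at 1.40 and cholesterol synthesis genes (0.0153) with Hmgcs1 at 0.98 were also higher by camera, with adjusted p = 0.585 with an estimated correlation. Lower were the cycling genes (camera adjusted p = 3.67e-24; adjusted p = 0.585 with an estimated correlation), 32 of 52 when adjusted over the list alone, with Cenpa at -2.38 and Ube2c at -2.58, and ribosomal protein genes (0.000105; adjusted p = 0.586 with an estimated correlation) with Rpl4 at -0.82. Camera did not call the other 11 lists (adjusted p between 0.0584 and 0.998); the receptor tyrosine kinase list held Dusp6 at 1.45. For the p53 targets the median was -0.19 while camera's direction was up. The lower level of cycling genes is partly circular here too, since such genes helped to make the clusters.

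Without tumour 4, which held no astrocyte-like cells, edgeR called 413 genes, 275 higher and 138 lower; with no filter on low counts it called 324 and with finer clusters 43. Without tumour 1 it called 0 (362 unadjusted), with tumour 2 alone holding both classes and the other sums giving the spread. On simulated counts at this size the test made 86 calls and recovered 5% of genes changed 2-fold and 71% of those changed 4-fold.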

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

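The tests of WPRE below were chosen after its levels were seen, except that of the spread of cells with 0 UMIs, whose outcome was named in advance. WPRE entered no comparison by design and there were no control samples, so its levels in cells outside the neural classes were set against the limit of a count of 0, and all 5 were above it. This shows that UMIs were present, not that the cells express WPRE, since free RNA was not removed.

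In microglia-like cells WPRE stood at 583.1 CPM in tumour 1, 431.7 in tumour 4 and 38.1 in tumour 2. T or NK cell-like cells of tumour 2 had 47.4 CPM, from 6 UMIs, and endothelial-like cells of tumour 2 had 580.5 CPM. OPC-like cells of the same tumours had 595.8, 847.1 and 687.0 CPM in tumours 1, 4 and 2.

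The level in microglia-like cells of tumours 1 and 4 may come from RNA of tumour cells in the same droplets, free or taken up, or from transcription in the microglia-like cells themselves. Transcription alone is argued against: genes of OPC-like cells that tumour 2's microglia-like cells nearly lacked stood in the microglia-like cells at a median of 0.557 of their OPC-like level in tumour 1 (140 genes) and 0.415 in tumour 4 (155 genes), and it would leave those genes near 0. Whether such RNA accounts for all of the WPRE stays open, since the median ratio of those genes was 0.570 of the ratio of WPRE in tumour 1 and 0.814 in tumour 4, where that account asked for agreement within 1.5-fold; tumour 4 met this and tumour 1 did not, so the test did not decide. Doublets could add to it, as none were removed here. A biological explanation, such as insertion of the transgene in a microglial cell, was not tested.

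WPRE was lower in oligodendrocyte-like than in OPC-like cells, at 266.1 against 687.0 CPM in tumour 2 and 595.7 against 847.1 in tumour 4. Among the oligodendrocyte-like clusters of tumour 2 it ran from 111.7 to 409.1 CPM. The oligodendrocyte-like cells were the deeper ones, with medians of 10351.5 against 6356.5 UMIs in tumour 2 and 11742 against 9420.5 in tumour 4. Whether cells that lack the transgene make up the whole of the difference was not decided. A mixture in which such cells have 0 UMIs would need more cells with 0 UMIs than were seen. The gap was 8.60 percentage points (bootstrap 95% interval 3.93 to 12.6) in tumour 2 and 13.4 (9.93 to 16.8) in tumour 4. But free RNA was not removed, so such cells need not have 0 UMIs. After thinning, 9.11% of microglia-like cells of tumour 2 and 40.3% of those of tumour 4 held a WPRE UMI. A smaller admixture stays open too: cells with 0 UMIs exceeded a Poisson count by 6.41 points in tumour 2 and 5.57 in tumour 4, against 8.18 (0.223 to 16.7) and 5.70 (4.28 to 7.17) in OPC-like cells. That the excess was no larger there had been named as the outcome without a mixture, but the intervals overlap, so this is left undecided. Lower transcription of the transgene in these cells is a candidate explanation that was not tested.

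The count of 564 genes between cycling and non-cycling cells was set against the other ways of splitting the 6 sums into 3 and 3, a test planned in advance. Of the 10 splits 1, the real one, gave as many, and the highest other count was 0, also among the other splits that part every pair. With 10 splits the share cannot fall under 0.05. Every other split also puts cycling and non-cycling sums on the same side, so their difference widens the spread. The counts of 0 therefore do not decide the question.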

How the results depend on the processing

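The alternatives named here were chosen in advance, except the removal of cells with the highest Scrublet scores, the clustering without haemoglobin genes, naming by marker level alone, the haemoglobin barcode kept in the profile, and the cycling share and list levels of OPC-like cells, which were chosen after seeing the data. Most results kept their direction and their side of the threshold: 427 of 532 values of named genes in the cycling test, 417 of 568 in the oligodendrocyte-like test, 211 of 294 in the astrocyte-like test and 124 of 189 list tests. These counts include values that were not called and stayed so, among them every kept value in the astrocyte-like test, where no gene was called. Of the 189 list tests, 59 lost the call that camera had given. Where results changed, the cause was not tested, save where named.

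With the tumours clustered together the mean share of OPC-like cells was 0%, that of oligodendrocyte-like cells 36.9% and that of unnamed cells 50.6%. The cycling share was 49.4% without thinning and 33.4% in OPC-like cells alone. Genes differing 8-fold between tumours numbered 76 in OPC-like cells alone, and the lists differing 2-fold numbered 11 in those cells and ranged from 1 to 7 as each tumour was left out.

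Calls between cycling and non-cycling cells numbered 2085 in OPC-like cells alone and 859 with DESeq2, and ranged from 343 to 4338 as each tumour was left out. Those between astrocyte-like and OPC-like cells numbered 298 with no filter on cells, 2 with at least 1000 genes and at most 10% mitochondrial UMIs, 159 without the highest Scrublet scores and 329 without haemoglobin genes; in these 4 settings only tumour 1 held both classes, so a lone sum was assumed to vary like the others. They were 43 at resolution 2, 1 with halved UMIs, 78 with DESeq2 and 324 with no filter on low counts, and ranged from 0 to 413 as tumours were left out. Between oligodendrocyte-like and OPC-like cells, the same settings in turn gave 1304, 15 (0 of them lower), 1467 and 1829, then 628 with halved UMIs, 418 with DESeq2 and 1171 with no filter on low counts, and 0 to 1723 as tumours were left out. At resolution 0.5, with joint clustering and without tumour 2, neither class test could be fitted.

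The replicate block changed the number of calls. Without it, 132 genes rather than 564 were called for cycling, 0 rather than 84 for oligodendrocyte-like cells and 0, as with it, for astrocyte-like cells; 15 of 38 named cycling genes and all 21 called genes named for oligodendrocyte-like cells lost their calls, and camera called 19 rather than 26 of 63 lists. Directions turned for p53 targets (adjusted p = 0.977) and surface targets of therapy (0.542) in astrocyte-like cells, and for interferon (0.609) and Wnt genes (0.609) in oligodendrocyte-like cells. With fry 1 list passed, and the p53 targets of astrocyte-like cells turned (0.853); with an estimated correlation 0 lists passed.

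In OPC-like cells alone Pdgfra turned to -0.29 (log2) and H3f3a to -0.0505 for cycling, and with thinned sums Pdgfra to -0.0850 and H3f3a to -0.00167. At resolution 2 Nusap1 (0.31), Aspm (0.20), Cdca8 (0.32), Birc5 (0.11), Prc1 (0.25) and Cenpe (0.36) turned in the oligodendrocyte-like test. Depth limits tumour 2 most, with 15231673 UMIs, and the classes of few cells, such as the 36 astrocyte-like cells of tumour 1.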

Other observations

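The genes and clusters below were chosen after their values were seen, and no test was made on them. In tumour 2 a cluster of 22 oligodendrocyte-like cells had high levels of p53 target genes: Mdm2 stood at 2771 CPM against 69.2 in the rest of the tumour, the cell cycle inhibitor Cdkn1a at 6662 against 301.2, Ccng1 at 992.0 against 37.6 and the cytokine Gdf15 at 725.8 against 13.7. Its median depth of 19161.5 UMIs was above the 7783 of all kept cells of the tumour. The casein genes Csn2 and Csn3, known from the mammary gland, were found in other oligodendrocyte-like clusters of tumour 2, with Csn2 at 872.8 CPM in a cluster of 68 cells and 302.1 in one of 179. The neuroblast-like cells of tumour 2 carried the interneuron factors Dlx1 at 501.5 CPM and Dlx2 at 331.8, against 15.7 for Dlx2 in the rest.

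Cells with OPC markers were not uniform. An unnamed cluster of 276 cells in tumour 1 with OPC markers had the neuropeptide precursor gene Vgf at 1242 CPM against 502.0 and the neurofilament Nefm at 376.0 against 105.2. In another unnamed cluster of tumour 1, with 241 cells and OPC markers, the interferon-responsive Gbp2 stood at 1201 CPM against 162.6, and Ly6a at 863.4 against 92.6; in a cluster of 57 OPC-like cells of tumour 4 Gbp2 stood at 2028 against 438.1 and Ifit3 at 842.2 against 248.2. Another OPC-like cluster of tumour 4, with 137 cells, had the neuronal factor Neurod1 at 105.2 CPM against 19.8 and the neuropeptide galanin, Gal, at 89.8 against 7.78.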
